A study of Rattus norvegicus with 15 samples.

How the data were processed

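RNA from cultured rat spermatogonial stem cells was hybridised to 15 single-colour arrays, 3 independent cultures in each of 5 groups: control with GDNF, 18 h of GDNF withdrawal, and withdrawal followed by 2, 4 or 8 h of GDNF replacement. The deposited values are probe set intensities on a linear scale, 1 column per sample, and per the submitters' processing notes the tools were GCRMA and Partek 6.3, without role or order. The linear scale was read from the values, which ranged too widely to be log2 values. GCRMA in general corrects background by probe sequence and normalizes arrays together, so low intensities depend on its background estimate; its settings are not given in the sources used here. The share of probe sets at or over the low-value level was 50.1% to 50.4% per array, and the 100 brightest probe sets held 16% to 16.6% of the summed intensity.

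Intensities were taken to log2 with no further normalization. The 57 control probe sets were left out, and a probe set was tested where its log2 intensity was at least 4 (16 on the linear scale) on at least 3 of the 15 arrays, which kept 15856 of 31099 (51.1%). Gene names came from the platform annotation supplied with the table, updated by gene identifier through a RefSeq gene table of assembly GRCr8 used for names alone. Of the probe sets 20832 had 1 symbol, 436 several and 9831 none, and 20764 of those with 1 symbol matched the table; no gene was named from a probe set with several symbols. A gene was represented by its tested probe set with the highest mean over all arrays. Genes whose probe sets were all under the low-value filter, such as Gfra1, Lhx1, Egr3, Tspan8 and Eomes, and list members without a probe set of 1 symbol are not analysed here.

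Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), all 15 arrays sharing 1 estimate of spread. There were 6 comparisons: withdrawal with control, each replacement time with withdrawal, and 8 h with control and with 2 h. An F test over the 5 groups and the overlap of falls on withdrawal with rises on replacement were added. P-values are two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. SD is over the 3 arrays of a group on the intensity scale unless log2 is stated, and SE is that of the limma log2 change.

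Before the data were examined, 21 gene lists were fixed: genes tied to GDNF in mouse, GDNF receptor and proximal signalling, ERK feedback, immediate early, undifferentiated spermatogonia, differentiating and meiotic, late germ cell, proliferation, arrest and apoptosis, FOXO targets, sterol synthesis, amino acid response, ribosome biogenesis, glycolysis and hypoxia, BMP and TGF-beta response, interferon, heat shock, and markers of Sertoli, mesenchymal (fibroblast or feeder), Leydig or peritubular, and immune or blood cells. The 19 lists with more than 1 tested gene were tested with camera at a preset correlation, 114 tests in all, beside an estimated correlation and fry. Camera compares a list with the other genes; fry does not. Calls were 33 with the preset and 10 with an estimated correlation.

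The rule for named genes, also fixed before the data were examined, took in each comparison the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, leaving out symbols that are only locus numbers. It added, in every comparison, all tested members of the GDNF-tied list, and Gfra1 and Ret, of which Gfra1 was not tested; up to 4 called members of each described list with the smallest adjusted p, or up to 2 as values; and 10 genes of the fall and rise set with the largest smaller fold. Members of the 4 that are named elsewhere in the same comparison are not repeated. Where another probe set of a named gene differed in call, or had a log2 change over 1.5 times larger or smaller, it is given.

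Settings tried were other filters and none, a floor at log2 4, median centring and quantile normalization, no intensity trend, array weights, only the groups compared, no multi-target probe sets, the replicate number as a block, and each array left out in turn. A mesenchymal marker covariate, 3 arrays left out together and the overlap without the 2 h arrays were added after the data were seen. These 3 arrays were replicate 1 of control, withdrawal and 4 h. They had the lowest values of the first component of variation within groups (-0.328, -0.482 and -0.393). Quality measures were compared with permutation tests in Python 3.11.15 with scipy 1.17.1.

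The steps were tested on simulated data with 200 of 15856 probe sets changed. For withdrawal against control, 26%, 76%, 92% and 100% of changes of 0.25, 0.5, 1 and 2 on the log2 scale were recovered, with 3 false calls. For 2 h against withdrawal 28%, 72%, 92% and 100% were recovered with 14 false calls (8.75% of its calls), and for 8 h against control 26%, 62%, 92% and 100% with 5. The other 3 comparisons had 5 to 8 false calls. In a simulated test over 9002 genes for withdrawal against control, camera called a list of 20 genes shifted by 0.5 and 0 of 19 other lists. The noise of each gene was drawn independently in all these simulations, so they do not gauge list calls among correlated genes.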

Results

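Rat spermatogonial stem cells, the germline stem cells of the testis, were grown for 1 month in serum-free medium with glial cell line-derived neurotrophic factor (GDNF), the ligand of the GFRA1 and RET receptors. Cultures were then kept with GDNF as the control, deprived of GDNF for 18 h, or deprived for 18 h and given GDNF back for 2, 4 or 8 h. Each of the 5 groups had 3 arrays from independent cultures, 15 arrays in all, and the comparisons ask which transcripts follow the loss and the return of GDNF. No group kept without GDNF to the times of replacement is analysed here. Handling at withdrawal was not tested apart from the loss of GDNF, which limits the comparisons with the control. Each array held 31099 probe sets, of which 50.1% to 50.4% per array had an intensity of at least 16, and the number of arrays limits the precision. After the low-value filter 15856 probe sets were tested, of which 12312 had 1 symbol and stood for 9002 named genes. Of the 15856 probe sets 7864 (49.6%) differed among the 5 groups. The residual SD per probe set had a median of 0.102 on the log2 scale, with quartiles of 0.0719 and 0.151.

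After GDNF withdrawal Bcl6b was 9.78-fold lower, at an intensity of 163.9 ± 26.4 against 1588 ± 52.4 in the control (SD, n = 3 in each group). Bcl6b is a transcriptional repressor known to respond to GDNF in mouse spermatogonial stem cells. Its log2 change was -3.29 ± 0.11 (SE, limma adjusted p = 2.36e-11), and its 3 other tested probe sets fell as well. Gpx2, a glutathione peroxidase, fell 4.92-fold, Fblim1 4.86-fold, the nitric oxide synthase Nos3 4.41-fold, Anxa3 4.27-fold, the hedgehog ligand Dhh 4.13-fold, Arap3 4.06-fold, the receptor gene Csf3r 3.96-fold, Ccsap 3.75-fold and Hoxc4 3.71-fold. The transcripts that rose most were the heat shock gene Hspa1a (5.88-fold, from 41.91 ± 7.94 to 244.7 ± 33, n = 3), Crip1 (3.54-fold) and the forkhead transcription factor gene Foxo3 (2.93-fold, from 215 ± 11.3 to 630 ± 32.6). Fam120c rose 2.69-fold, the pro-apoptotic gene Bik 2.68-fold, Rac2 2.67-fold, Atoh8 2.38-fold, Crip2 2.29-fold, the Notch target Hey1 2.22-fold and Sulf2 2.14-fold. Adjusted p ranged from 1.5e-12 to 4.07e-05 over these 20 genes. A further probe set of Hoxc4 fell by only 0.41 on the log2 scale (adjusted p = 0.00771). The mean log2 intensity of 7 Sertoli cell markers, Dhh among them, was 6.628 ± 0.022 in the control and 6.259 ± 0.065 after withdrawal (SD, n = 3; permutation adjusted p = 0.0069 over the 5 groups), and 6.299 ± 0.014, 6.339 ± 0.028 and 6.321 ± 0.053 at 2, 4 and 8 h. Without Dhh the mean of the other 6 was 6.731 ± 0.022 in the control, 6.642 ± 0.077 after withdrawal and 6.688 ± 0.012, 6.732 ± 0.031 and 6.697 ± 0.054 at these times, a comparison added after the data were seen and not tested. Of the 7 markers 2 fell and 1 rose, also adjusted over the list alone, with a median log2 change of -0.10 (camera adjusted p = 0.16).

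The ERK feedback list holds genes known to be induced by ERK signalling. Of its named members Spry4, Spry2, Dusp5 and Dusp6 encode inhibitors of the pathway, Errfi1 an inhibitor of the EGF receptor, Etv4 and Fosl1 transcription factors and Epha2 a receptor. After withdrawal 8 of 13 tested members were lower and 1 was higher (camera adjusted p = 3.61e-05; adjusted p = 0.0151 with an estimated correlation). The counts were the same adjusted over the list alone. Spry4 fell 2.96-fold, Dusp6 1.6-fold, Etv4 1.37-fold and Epha2 1.34-fold. Of 21 immediate early genes, which respond to growth factors without new protein synthesis, 11 fell and 1 rose, the same counts adjusted over the list alone (adjusted p = 3.1e-05; adjusted p = 0.109 with an estimated correlation). Among them Arc fell 1.75-fold, Klf10 1.72-fold, Zfp36 1.7-fold and Egr1 1.59-fold. Of 10 genes tied to GDNF by other studies in mouse, 5 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.00104; adjusted p = 0.0662 with an estimated correlation). Besides Bcl6b and Etv4, Ccnd2 fell 1.96-fold, Id4 1.6-fold and Etv5 1.46-fold, while Cxcr4 rose 1.3-fold. The call of Cxcr4 was lost without control replicate 2 or 3 or withdrawal replicate 1 or 2 (adjusted p = 0.0671, 0.0589, 0.0677 and 0.0536), and its other probe sets were not past the threshold (adjusted p = 0.628 and 0.283). Of the other probe sets of Id4, 1 fell by 0.33 on the log2 scale and 1 was at -0.05 (adjusted p = 0.0372 and 0.898), and that of Etv4 was at -0.81. Of the rest, the log2 change was -0.25 for Pou3f1, -0.35 for Egr2, -0.23 for Fos and -0.01 for Mycn, none past the threshold.

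The GDNF receptor and proximal signalling list had 6 members lower and 1 higher of 15 (camera adjusted p = 0.0123; adjusted p = 0.0662 with an estimated correlation and 0.127 without the low-value filter), also adjusted over the list alone. Ret, the signalling receptor, was 1.14-fold lower, Pik3cd 2.03-fold and Gfra2 1.58-fold lower, and the adaptor gene Gab1 was 1.28-fold higher. The other probe sets of Ret, at log2 changes of -0.06 and -0.16, were not past the threshold (adjusted p = 0.597 and 0.0806), and that of Pik3cd was at -0.61. Sterol synthesis genes were lower in 8 of 19 members and higher in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00244), and this adjusted p was 0.271 with an estimated correlation. The lanosterol demethylase gene Cyp51 fell 1.24-fold, Msmo1 1.35-fold, Idi1 1.24-fold and Insig1 1.31-fold. The other probe set of Idi1 was at a log2 change of -0.48, and that of Cyp51, at -0.26, was not past the threshold (adjusted p = 0.0706). Of 19 genes listed as FOXO targets, 7 were higher and 2 lower (8 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.116). Without the low-value filter camera called it upward (adjusted p = 0.0204). Ddit4, an inhibitor of mTORC1 signalling, rose 1.46-fold and the receptor gene Igf1r 1.24-fold, while Trib1 fell 3.6-fold and Cited2 1.56-fold.

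In all, 3342 probe sets differed between withdrawal and control by limma, 1809 higher and 1533 lower after withdrawal, and 21 rose and 122 fell at least 2-fold. The groups did not overlap for 34.3% of tested probe sets, against 10% by chance. With only the 6 arrays of these groups in the fit, 2166 probe sets were called, and Ret and Etv5 were no longer among the genes past the threshold (adjusted p = 0.062 and 0.064). With values under 16 set to 16, the changes of genes near that level shrank, to 2.48-fold for Anxa3, 2.37-fold for Ccsap, 1.44-fold for Fam120c and 1.26-fold for Atoh8. The 5S ribosomal RNA control probe set, outside the test, had an intensity of 1263 ± 58.4 in the control, 2044 ± 45.8 after withdrawal and 1682 ± 28.4, 1444 ± 165 and 1258 ± 29.8 at 2, 4 and 8 h (SD, n = 3; permutation adjusted p = 0.00033 on the log2 scale). The 3′ minus 5′ log2 difference of the GAPDH control probe sets, a sign of RNA quality, was -0.197 ± 0.01, -0.118 ± 0.031, -0.266 ± 0.011, -0.144 ± 0.028 and -0.156 ± 0.021 in the same order (SD, n = 3; permutation adjusted p = 0.00148). That of the hexokinase control probe sets was 2.496 ± 0.052, 2.425 ± 0.029, 2.243 ± 0.106, 2.206 ± 0.062 and 2.336 ± 0.148 (permutation adjusted p = 0.0334), and the beta-actin difference was not past the threshold (0.102). The mean log2 intensity of the hybridization spikes was 9.825 ± 0.222, 10.112 ± 0.153, 9.89 ± 0.165, 10.145 ± 0.071 and 10.323 ± 0.103 (permutation adjusted p = 0.0328). That of 15 heat shock genes was 10.643 ± 0.03, 10.773 ± 0.014, 10.683 ± 0.009, 10.743 ± 0.035 and 10.638 ± 0.042 (permutation adjusted p = 0.00169).

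**Figure D1:**
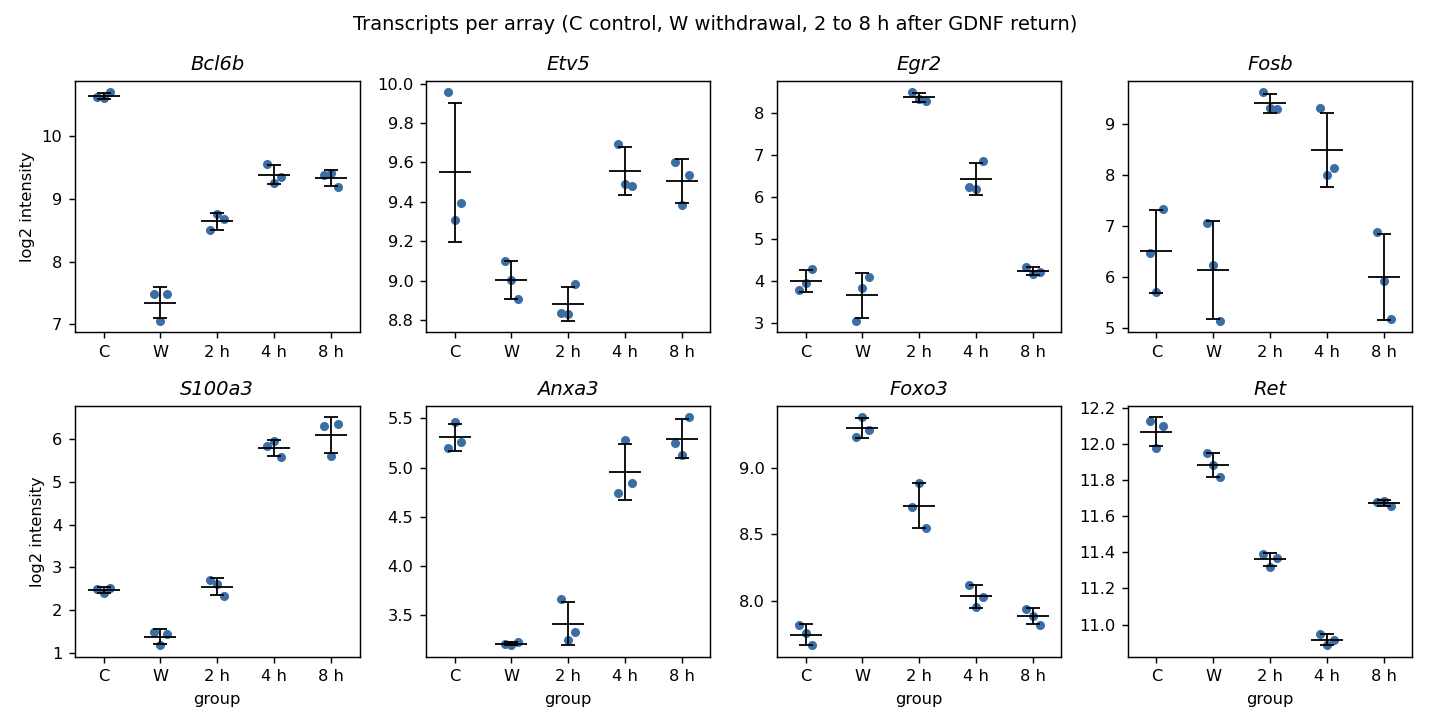
Log2 intensity of 8 transcripts on each array in control (C), withdrawal (W) and 2, 4 and 8 h after GDNF return; dots are arrays, bars the mean with its SD over 3 arrays. Bcl6b fell 9.78-fold on withdrawal and was 2.46-, 4.1- and 3.95-fold above withdrawal at 2, 4 and 8 h, while Egr2 rose 26.1-fold at 2 h.

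At 2 h after GDNF return, the zinc-finger transcription factor gene Egr2 had risen 26.1-fold over withdrawal, from an intensity of 13.2 ± 4.5 to 330.4 ± 24 (SD, n = 3), a log2 change of 4.71 ± 0.23 (SE, limma adjusted p = 4.08e-09). The AP-1 component genes Fosb and Junb rose 9.55- and 4.34-fold, the 14-3-3 sigma gene Sfn 6.85-fold and the EGF-family ligand gene Hbegf 5.59-fold. Trib1 rose 3.83-fold, Fhl2 3.78-fold, the activin subunit gene Inhba 3.73-fold, Smad7, an inhibitor of TGF-beta signalling, 3.51-fold and Epb41l5 3.43-fold. The transcripts that fell most were Pdgfra (3.15-fold), Atoh8 (3.08-fold), Meis1 (3.04-fold), Hspa1a (2.98-fold), Hoxa5 (2.84-fold) and Zfhx4 (2.78-fold). Chac1 fell 2.57-fold, Cdkl4 2.45-fold, Fam120c 2.44-fold and Rnf125 2.43-fold, and adjusted p for the 20 genes ranged from 2.9e-11 to 0.00496. The other probe set of Zfhx4 fell by 0.82 on the log2 scale (adjusted p = 0.0254).

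Of 21 immediate early genes 15 rose and 1 fell at 2 h (17 and 1 adjusted over the list alone; camera adjusted p = 3.2e-13; adjusted p = 0.0148 with an estimated correlation). Besides Egr2 and Junb, Egr1 rose 2.71-fold and Klf10 2.22-fold. Genes of the ERK feedback list rose in 8 of 13 members and fell in 1, also adjusted over the list alone (adjusted p = 3.73e-06; adjusted p = 0.00854 with an estimated correlation). Dusp5 rose 2.8-fold, Dusp6 1.87-fold, Epha2 1.65-fold and Spry4 1.63-fold. Sterol synthesis genes rose in 11 of 19 and fell in 0, also adjusted over the list alone (adjusted p = 8.17e-09; adjusted p = 0.0431 with an estimated correlation). Idi1 rose 2.27-fold, Msmo1 1.95-fold, the squalene epoxidase gene Sqle 1.64-fold and Cyp51 1.52-fold, whose other probe set rose by 0.38 on the log2 scale. In the BMP and TGF-beta response list 6 of 10 genes rose and 2 fell (7 and 2 adjusted over the list alone; adjusted p = 8.27e-05; adjusted p = 0.0431 with an estimated correlation). Id1 rose 2.62-fold, Hes1 2.39-fold and Skil 2.16-fold.

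Of the 10 GDNF-tied genes 6 rose and 1 fell at 2 h (7 and 1 adjusted over the list alone; adjusted p = 0.00147; adjusted p = 0.0481 with an estimated correlation). Bcl6b rose 2.46-fold, Fos 2.44-fold, Id4 2-fold, Pou3f1 1.42-fold and Etv4 1.19-fold, while Cxcr4 fell 2.12-fold. Of the other probe sets of Id4, 1 rose by 0.56 on the log2 scale and 1, at 0.29, was not past the threshold (adjusted p = 0.0346 and 0.0605). The call of Etv4 was lost without withdrawal replicate 2 or 3 (adjusted p = 0.126 and 0.123), without 2 h replicate 1, 2 or 3 (0.0838, 0.0745 and 0.0792), without the low-value filter (0.0906) and without the intensity trend (0.0584), while its other probe set rose by 0.33 on the log2 scale (0.0038). The log2 change was 0.26 for Ccnd2, -0.12 for Etv5 and -0.05 for Mycn, none past the threshold, though Ccnd2 was without withdrawal replicate 2 (adjusted p = 0.033). Ret fell 1.44-fold, and its list had 2 members higher and 3 lower of 15 (camera adjusted p = 0.811; 3 and 3 adjusted over the list alone), with the adaptor gene Frs2 1.2-fold higher and Gab1 1.17-fold lower. The other member called higher was Gfra3, whose intensity was under 16 on all arrays of both groups, so no fold is given, and its call was lost without withdrawal replicate 2 (adjusted p = 0.0626). Mesenchymal markers were lower in 5 of 16 tested members and higher in 0, also adjusted over the list alone (adjusted p = 0.0461; adjusted p = 0.838 with an estimated correlation and 0.101 without the low-value filter), among them Pdgfra, Col3a1 (1.46-fold), Col5a1 (1.43-fold) and Col1a1 (1.38-fold). The other probe sets of Frs2, Col5a1 and Col1a1, at log2 changes of 0.15, -0.33 and -0.07, were not past the threshold (adjusted p = 0.496, 0.199 and 0.571). The calls of Col3a1 and Col5a1 were lost without withdrawal replicate 2 (adjusted p = 0.163 and 0.0792) or 3 (0.0975 and 0.152), without 2 h replicate 1 (0.139 and 0.143), without the low-value filter (0.0945 and 0.0958) and with only the groups compared (0.0695 and 0.0596). That of Col3a1 was also lost without 2 h replicate 3 (0.0715), and that of Col5a1 without 2 h replicate 2 (0.0967).

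Limma called 4137 probe sets at 2 h, 1888 higher and 2249 lower than after withdrawal, with 113 up and 51 down at least 2-fold. Centring each array on its median gave 2185 higher and 1950 lower. Without withdrawal replicate 2 the split was 1360 higher and 1472 lower. The mean log2 intensity of the 16 mesenchymal markers was 8.483 ± 0.234 in the control, 8.344 ± 0.437 after withdrawal, and 7.918 ± 0.118, 8.176 ± 0.291 and 8.6 ± 0.1 at 2, 4 and 8 h (SD, n = 3; permutation p = 0.0844, adjusted 0.102 over 11 measures). Across arrays within groups, Inhba, Hbegf, Pdgfra, Meis1, Hoxa5 and Zfhx4 followed this mean with log2 slopes of 1.91, 1.39, 1.37, 1.28, 1.63 and 1.44, and Fosb, Fos and Etv4 with slopes of -2.04, -1.40 and -0.33 (limma adjusted p from 1.81e-06 to 0.0297). With this mean as a covariate, chosen after the data were seen, Fos, Etv4, Col3a1 and Col5a1 were no longer past the threshold at 2 h (limma adjusted p = 0.0675, 0.252, 0.261 and 0.264), and leaving out withdrawal replicate 3 also ended the call of Fos (adjusted p = 0.0546). Col3a1, Col5a1 and Pdgfra are themselves part of this mean, so the covariate takes away change that they share with it. With the covariate Ccnd2, at a log2 change of 0.44, was past the threshold (adjusted p = 0.00383). Under the covariate Fosb was 5.22-fold, Hbegf 8.44-fold and Inhba 6.57-fold higher, and Hoxa5 and Zfhx4 were 1.76- and 1.81-fold lower. With values under 16 set to 16, Hbegf rose 2.3-fold, Epb41l5 2.28-fold and Fhl2 1.52-fold, and Fam120c and Atoh8 fell 1.44- and 1.26-fold.

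**Figure D2:**
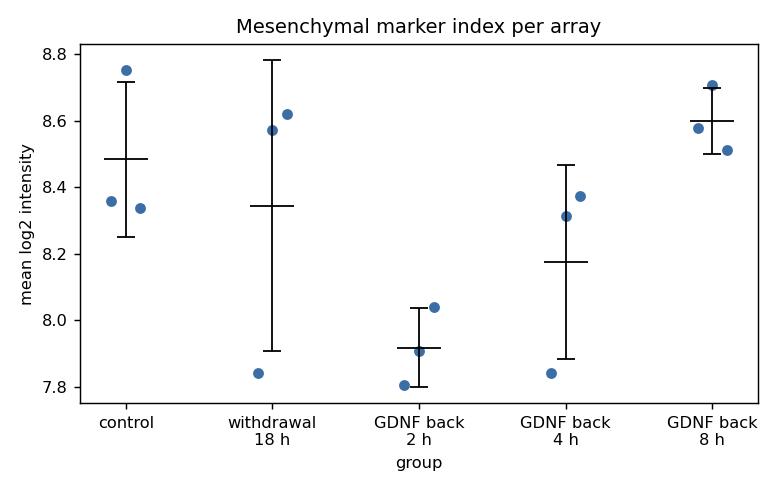
Mean log2 intensity of the 16 tested mesenchymal markers on each array; dots are arrays, bars the group mean with its SD over 3 arrays. The mean was 7.918 at 2 h and 8.6 at 8 h, and the lowest withdrawal array and the lowest array at 4 h were both at 7.84.

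At 4 h after GDNF return, S100a3, a calcium-binding protein gene, stood 21.2-fold over withdrawal (55.35 ± 6.9 against 2.614 ± 0.304, SD, n = 3; log2 change 4.40 ± 0.18 SE, limma adjusted p = 1.5e-10). Sfn had risen 16.9-fold, the myosin gene Myh2 9.85-fold, the urokinase receptor gene Plaur 7.65-fold, Egr2 6.79-fold and the sphingosine kinase gene Sphk1 6.66-fold. The Wnt pathway transcription factor gene Tcf7l2 rose 5.87-fold, Iqsec3 5.49-fold, Fhl2 5.31-fold and Fosb 5.05-fold. Bik fell 4.09-fold, Rnf125 3.99-fold, Atoh8 3.98-fold, Clcc1 3.7-fold, Synm 3.7-fold and Hspa1a 3.5-fold, and Fam110b, Plpp7, Slc35f2 and Flvcr2 fell 3.48-, 3.15-, 3.13- and 3.13-fold. Ret was 1.96-fold below withdrawal (1932 ± 40.8 against 3779 ± 172), and its other tested probe sets fell as well. A further probe set of Fam110b fell by 0.66 on the log2 scale (adjusted p = 0.00164), and Plaur followed the mesenchymal marker mean within groups with a log2 slope of 1.41 (adjusted p = 0.000105).

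At 4 h 9 of 13 members of the ERK feedback list were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 5.49e-07; adjusted p = 0.00455 with an estimated correlation). Fosl1 rose 2.71-fold, Epha2 2.27-fold, Dusp6 2.25-fold and Spry4 1.89-fold. Immediate early genes were higher in 15 of 21 and lower in 0, also adjusted over the list alone (adjusted p = 3.3e-10; adjusted p = 0.0232 with an estimated correlation), including Junb (3.75-fold), Maff (3.15-fold), Klf10 (2.37-fold) and Egr1 (2.2-fold). Of the 10 GDNF-tied genes 7 rose and 1 fell, also adjusted over the list alone (adjusted p = 3.7e-05; adjusted p = 0.0232 with an estimated correlation). Bcl6b rose 4.1-fold, Ccnd2 2.33-fold, Pou3f1 2.11-fold, Id4 1.84-fold, Etv4 1.48-fold and Etv5 1.46-fold, and Cxcr4 fell 1.38-fold. The other probe sets of Id4, at log2 changes of 0.26 and 0.45, and 1 of Cxcr4, at -0.69, were not past the threshold (adjusted p = 0.0836, 0.0762 and 0.0698), and a further probe set of Cxcr4 was at -0.83 (0.0147). The log2 change was 0.52 for Fos and 0.00298 for Mycn, neither past the threshold.

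The receptor and proximal signalling list had 5 members higher and 2 lower of 15 at 4 h (6 and 2 adjusted over the list alone; camera adjusted p = 0.0446; adjusted p = 0.107 with an estimated correlation). Gfra3 was 3.76-fold and Dok5 2.24-fold higher (1.92- and 1.18-fold with values under 16 set to 16), and Gab1 1.24-fold lower. This list was also not called with the mean over the probe sets of a gene (adjusted p = 0.26), without the low-value filter (0.139) and, chosen after the data were seen, with the mesenchymal marker mean as a covariate (0.0522) or 3 arrays left out (0.0999). Sterol synthesis genes were higher in 10 of 19 and lower in 2, also adjusted over the list alone (adjusted p = 9.87e-05; adjusted p = 0.152 with an estimated correlation), among them Insig1 (1.61-fold), Msmo1 (1.53-fold), Idi1 (1.5-fold) and Cyp51 (1.4-fold). BMP and TGF-beta response genes were higher in 6 of 10 and lower in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.00111; adjusted p = 0.102 with an estimated correlation). Id1 rose 2.51-fold, Skil 2.28-fold and Hes1 2.21-fold. Proliferation genes, which act from S phase to mitosis, were lower in 16 of 33 and higher in 0 (18 and 0 adjusted over the list alone; adjusted p = 0.00231; adjusted p = 0.23 with an estimated correlation). Nusap1 was 1.59-fold lower, Kif20a 1.33-fold, the cyclin gene Ccnb2 1.29-fold and Bub1b 1.24-fold lower.

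Limma called 4848 probe sets at 4 h, 2314 higher and 2534 lower than after withdrawal, with 176 up and 75 down at least 2-fold; centring on the median gave 2666 higher and 2159 lower. The withdrawal level of S100a3 lay under the low-value level, and with values under 16 set to 16 it rose 3.44-fold, Myh2 5-fold, Sphk1 2.42-fold and Fhl2 2.13-fold, and Atoh8 fell 1.26-fold.

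At 8 h after GDNF return, S100a3 was 26.1-fold and Myh2 12.2-fold above withdrawal (limma adjusted p = 2.86e-10 and 1.45e-08; log2 changes 4.71 ± 0.18 and 3.61 ± 0.21 SE, n = 3 arrays in each group). The hypoxia-inducible factor gene Epas1 rose 5.42-fold (305.8 ± 25.1 against 56.39 ± 3.37), Plcd4 5.38-fold, Plaur 5.26-fold, Fblim1 5.18-fold, RT1-T24-4 4.38-fold, Anxa3 4.24-fold, Ccsap 4.14-fold and Gfra3, a receptor of the GDNF receptor family, 4.12-fold. The transcripts that fell most were Hspa1a (4.7-fold), Bik (3.13-fold), Slc24a4 (2.86-fold), Zcchc18 (2.71-fold), Foxo3 (2.67-fold) and Crip2 (2.67-fold). Krt12 fell 2.54-fold, Rac2 2.51-fold, Vat1 2.5-fold and Atoh8 2.44-fold.

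At 8 h 9 of 13 members of the ERK feedback list were higher than after withdrawal and 0 lower, also adjusted over the list alone (camera adjusted p = 5.32e-07; adjusted p = 0.00379 with an estimated correlation). Spry4 was 2.17-fold, Fosl1 1.94-fold, Epha2 1.77-fold and Dusp6 1.75-fold higher. Immediate early genes were higher in 11 of 21 and lower in 0 (13 and 0 adjusted over the list alone; adjusted p = 4.28e-06; adjusted p = 0.0683 with an estimated correlation). Klf10 was 1.84-fold, Junb 1.8-fold, Egr1 1.46-fold and Zfp36 1.45-fold higher. Of the 10 GDNF-tied genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.000593; adjusted p = 0.0642 with an estimated correlation). Bcl6b was 3.95-fold, Ccnd2 2.15-fold, Id4 1.79-fold, Etv5 1.42-fold, Pou3f1 1.37-fold and Etv4 1.36-fold higher, and Cxcr4 1.32-fold lower. The call of Cxcr4 was lost without 8 h replicate 2 or 3 (adjusted p = 0.0511 and 0.053), and that of Pou3f1 without withdrawal replicate 3 (0.0671). The other probe sets of Cxcr4, at log2 changes of -0.12 and -0.61, were not past the threshold (0.804 and 0.0707). Of the other probe sets of Id4, 1 rose by 0.35 on the log2 scale and 1, at 0.29, was not past it (adjusted p = 0.0265 and 0.269). That of Etv4 rose by 0.77 on the log2 scale (adjusted p = 2.14e-06). Egr2, at a log2 change of 0.58, Fos, at -0.03, and Mycn, at -0.09, were not past the threshold, though Egr2 was without withdrawal replicate 3 (adjusted p = 0.0224). Receptor and proximal signalling genes were higher in 5 of 15 and lower in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.0131; adjusted p = 0.0642 with an estimated correlation and 0.0513 with the mean over the probe sets of a gene). Gfra2 was 1.73-fold and the adaptor gene Shc1 1.19-fold higher, and Ret 1.16-fold lower, with its other probe sets at log2 changes of -0.60 and -0.55.

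FOXO target genes were lower in 10 of 19 members and higher in 1 at 8 h (12 and 1 adjusted over the list alone; camera adjusted p = 0.00267; adjusted p = 0.0642 with an estimated correlation). Ccng2 was 1.55-fold, Igf1r 1.45-fold, Cat 1.39-fold and Txnip 1.28-fold lower. Proliferation genes were lower in 17 of 33 and higher in 0 (19 and 0 adjusted over the list alone; adjusted p = 0.000261; adjusted p = 0.151 with an estimated correlation), with Nusap1 1.53-fold, Bub1b 1.33-fold, Ccnb2 1.24-fold and Rrm1 1.23-fold lower. BMP and TGF-beta response genes were higher in 6 of 10 and lower in 2, also adjusted over the list alone (adjusted p = 0.0131; adjusted p = 0.151 with an estimated correlation). Smad7 was 2.11-fold, Skil 1.69-fold and Id3 1.51-fold higher. Mesenchymal markers were higher in 2 of 16, Fstl1 (1.5-fold) and Fbn1 (1.31-fold; adjusted p = 0.0503 without 8 h replicate 2), and lower in 0, also adjusted over the list alone (adjusted p = 0.0131; adjusted p = 0.62 with an estimated correlation, and 0.488 with 3 arrays left out), and the other probe set of Fstl1, at a log2 change of 0.24, was not past the threshold (adjusted p = 0.292). Sterol synthesis genes were higher in 2 of 19 and lower in 5, also adjusted over the list alone (adjusted p = 0.547). Acat2 was 1.44-fold, Dhcr7 1.38-fold and Fdft1 1.16-fold lower, and Msmo1 1.2-fold higher, and the other probe set of Fdft1, at -0.18, was not past the threshold (adjusted p = 0.0869).

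Limma called 3963 probe sets at 8 h, 1526 higher and 2437 lower than after withdrawal, and with each array centred on its median the split was 1961 higher and 1915 lower. With values under 16 set to 16, S100a3 rose 4.24-fold, Myh2 6.21-fold, Ccsap 2.61-fold, Anxa3 2.46-fold, Gfra3 2.1-fold and Atoh8 fell 1.26-fold, while Plcd4, at 2.1-fold, was not past the threshold (adjusted p = 0.068).

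**Figure D3:**
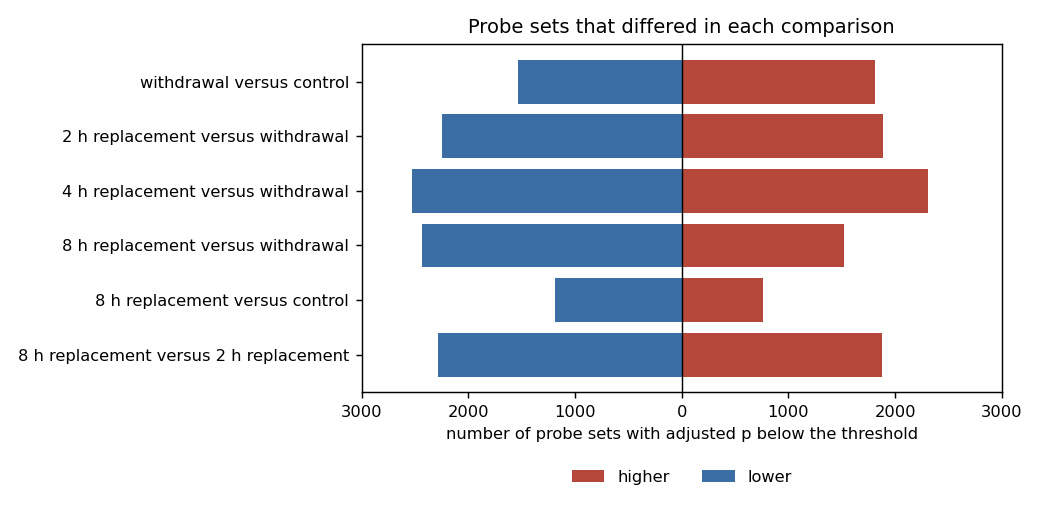
Number of probe sets with an adjusted p under 0.05 in each comparison, those higher in the first-named group to the right and those lower to the left. The comparison of 4 h with withdrawal had 4848 such probe sets and that of 8 h with the control 1953.

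Set against the control, the arrays at 8 h show which transcripts differed from cultures that were never deprived of GDNF. Bcl6b remained 2.47-fold lower (643.4 ± 52.7 against 1588 ± 52.4, SD, n = 3; limma adjusted p = 2.46e-06) and Dhh 3.84-fold lower, while S100a3 was 12.2-fold and Myh2 11.8-fold higher than in the control. Hbegf was 4.22-fold, Inhba 3.16-fold, Pcdh19 3.14-fold, C1ql1 2.92-fold, Plcd4 2.86-fold, Igsf5 2.76-fold, Plaur 2.58-fold and Iqsec3 2.55-fold higher. The liver X receptor gene Nr1h3 was 2.98-fold, Gatc 2.75-fold, Inka2 2.72-fold, Cyp2c23 2.71-fold, Flvcr2 2.69-fold, the innate receptor gene Tlr2 2.57-fold, Hoxc5 2.53-fold and Col25a1 2.53-fold lower. Ret was 1.32-fold lower (adjusted p = 3.19e-05), with its other probe sets at log2 changes of -0.67 and -0.71. The log2 changes of Ccnd2 (0.14), Etv4 (-0.01), Etv5 (-0.04), Id4 (0.16), Pou3f1 (0.20), Cxcr4 (-0.02), Egr2 (0.23), Fos (-0.26) and Mycn (-0.11) were not past the threshold.

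Proliferation genes were lower than in the control in 15 of 33 members and higher in 1 (19 and 1 adjusted over the list alone; camera adjusted p = 7.66e-07; adjusted p = 0.165 with an estimated correlation). The transcription factor gene Foxm1 was 1.51-fold, Aurkb 1.34-fold, Nusap1 1.25-fold and Rrm1 1.19-fold lower, but the other probe set of Foxm1, at a log2 change of -0.19, was not past the threshold (adjusted p = 0.607). With each array centred on its median, 8 members were lower, and as deposited 8 were without control replicate 3 and 7, 8 and 9 without 8 h replicate 1, 2 and 3. Sterol synthesis genes were lower in 10 of 19 and higher in 0 (12 and 0 adjusted over the list alone; adjusted p = 7.66e-07; adjusted p = 0.165 with an estimated correlation). Dhcr7 was 1.34-fold, Fdft1 1.27-fold, Cyp51 1.19-fold and Fdps 1.17-fold lower. The other probe sets of Fdft1 and Cyp51, at -0.22 and -0.19, were not past the threshold (adjusted p = 0.0586 and 0.244). Of the ERK feedback list 3 of 13 members were higher and 3 lower (4 and 3 adjusted over the list alone; adjusted p = 0.202). Errfi1 was 1.53-fold and Epha2 1.32-fold higher, and Spry4 1.36-fold and Spry2 1.18-fold lower. The call of Spry2 was lost without control replicate 1 or 2 or 8 h replicate 1 or 2 (adjusted p = 0.0962, 0.0944, 0.126 and 0.0823), with median centring (0.0606), quantile normalization (0.0577) or no low-value filter (0.0667), and with only the groups compared (0.107) or 3 arrays left out (0.113). The list had a median log2 change of -0.01 and a mean of 0.06. Of the 10 GDNF-tied genes only Bcl6b passed the threshold, also adjusted over the list alone (adjusted p of the list = 0.897). Within groups Inhba, Hbegf, Pcdh19, Plaur and Tlr2 followed the mesenchymal marker mean with log2 slopes of 1.91, 1.39, 1.86, 1.41 and 1.67, and Hoxc5 with -0.89 (adjusted p from 4.9e-05 to 0.0207). That mean was 8.483 ± 0.234 in the control and 8.6 ± 0.1 at 8 h (SD, n = 3 arrays).

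Limma called 1953 probe sets between 8 h and the control, 766 higher and 1187 lower, and 1241 with only these 2 groups in the fit. Centring on the median gave 1028 higher and 939 lower. Without 8 h replicate 1 the split was 452 higher and 860 lower. With values under 16 set to 16, S100a3 was 4.24-fold, Myh2 6.21-fold and C1ql1 1.49-fold higher, Nr1h3 1.91-fold and Tlr2 1.68-fold lower, and Hbegf (1.42-fold, adjusted p = 0.138) and Plcd4 (adjusted p = 0.104) were not past the threshold. Inhba was no longer called without control replicate 3 (adjusted p = 0.0603) or 8 h replicate 1 (adjusted p = 0.053). Plcd4 was not called without any 1 of control replicates 1, 2 and 3 or 8 h replicates 1 and 3 (adjusted p = 0.0777, 0.0741, 0.083, 0.117 and 0.151). Nor was Plcd4 called with no low-value filter (0.1), with no intensity trend (0.0546) or with only these groups in the fit (0.0847).

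Between 2 h and 8 h after GDNF return, Egr2 and Fosb fell while S100a3 and Myh2 rose 11.6- and 9.28-fold. Egr2 was 17.5-fold lower at 8 h than at 2 h (18.91 ± 1.19 against 330.4 ± 24, SD, n = 3; limma adjusted p = 1.92e-08), Fosb 10.6-fold, the syntaxin gene Stx11 3.56-fold, Epb41l5 3.25-fold, Fos 2.49-fold and Junb 2.42-fold. Gatc, Cep15, Cryl1 and Trib1 were 2.35-, 2.15-, 2.14- and 2.13-fold lower. Fblim1 was 5.36-fold, Plcd4 4.5-fold, Epas1 4.15-fold, Gpd1l1 4.14-fold, Meis1 4.1-fold, Ccsap 3.94-fold, the transketolase gene Tkt 3.8-fold and Anxa3 3.68-fold higher. Ccnd2 (1.8-fold), Bcl6b (1.61-fold), Cxcr4 (1.61-fold), Etv5 (1.54-fold) and Ret (1.24-fold) were higher at 8 h as well, while Etv4, Id4, Pou3f1 and Mycn, at log2 changes of 0.20, -0.16, -0.06 and -0.05, were not past the threshold. Etv4 was past it with only the groups compared (adjusted p = 0.0278), with array weights (0.0366) and, chosen after the data were seen, with the mesenchymal covariate (log2 change 0.42, adjusted p = 0.00257) or 3 arrays left out (0.036). The GDNF-tied list had 4 members higher and 2 lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.399), a median of 0.07 and a mean of -0.27. The other probe sets of Ret went the other way, at -0.15 and -0.09, and were not called (adjusted p = 0.168 and 0.333), that of Cep15 was at 0.03 (0.835), that of Etv4 rose by 0.44 on the log2 scale (0.000393), and 1 of Cxcr4 by 1.30 (0.00296).

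Immediate early genes were lower at 8 h than at 2 h in 13 of 21 members and higher in 2, also adjusted over the list alone (camera adjusted p = 2.7e-05; adjusted p = 0.175 with an estimated correlation), among them Egr1 (1.86-fold) and Srf (1.7-fold). Sterol synthesis genes were lower in 13 of 19 and higher in 0 (14 and 0 adjusted over the list alone; adjusted p = 4.06e-11; adjusted p = 0.0754 with an estimated correlation). Idi1 was 2.07-fold, Sqle 1.72-fold, Msmo1 1.63-fold and Cyp51 1.45-fold lower, with the other probe set of Cyp51 at a log2 change of -0.30. Mesenchymal markers were higher in 11 of 16 and lower in 0 (12 and 0 adjusted over the list alone; adjusted p = 5.62e-06; adjusted p = 0.356 with an estimated correlation), including Pdgfra (2.45-fold), Fstl1 (1.67-fold), Fbn1 (1.61-fold) and Col1a1 (1.45-fold). The other probe set of Fstl1 was at a log2 change of 0.43, and that of Col1a1, at 0.01, was not past the threshold (adjusted p = 0.924). Their mean went from 7.918 ± 0.118 at 2 h to 8.6 ± 0.1 at 8 h (SD, n = 3 arrays), and within groups Meis1, Tkt, Fosb and Fos followed it with log2 slopes of 1.28, 0.90, -2.04 and -1.40. Proliferation genes were lower in 10 of 33 and higher in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.0165; adjusted p = 0.356 with an estimated correlation, 0.0533 with the mean over the probe sets of a gene and 0.158 with the mesenchymal covariate). Nusap1 was 1.3-fold, Bub1b 1.21-fold and Ccnb1 1.2-fold lower, and Cdt1 1.17-fold higher. Receptor and proximal signalling genes were higher in 7 of 15 and lower in 1 (8 and 2 adjusted over the list alone; adjusted p = 0.0215; adjusted p = 0.137 with an estimated correlation and 0.0533 with the mean over the probe sets of a gene). Gfra3 was 2.53-fold and Gfra2 1.78-fold higher, and Frs2 1.14-fold lower, whose other probe set, at -0.08, was not past the threshold (adjusted p = 0.758).

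Limma called 4157 probe sets between 8 h and 2 h, 1874 higher and 2283 lower, and 2329 with the mesenchymal marker mean as a covariate, of which 1885 were among the 4157 (45.3% of them). That mean did not overlap between these groups (at most 8.041 at 2 h and at least 8.512 at 8 h). The covariate therefore takes up part of this contrast, and Pdgfra and Col1a1 are part of the mean. A call lost under it does not show a mesenchymal source. Under that covariate Fos, Trib1 and Cryl1, at log2 changes of -0.36, -0.43 and -0.83, were not past the threshold (adjusted p = 0.488, 0.323 and 0.0541), nor were Pdgfra, Col1a1 and Frs2, at 0.361, 0.205 and -0.131 (adjusted p = 0.0565, 0.112 and 0.166), Fosb was 4.02-fold lower, and Meis1 and Tkt were 2.24- and 2.52-fold higher. With values under 16 set to 16, S100a3 was 4.24-fold and Ccsap 2.61-fold higher, Stx11 1.3-fold lower, and Plcd4 not past it (adjusted p = 0.066).

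Most probe sets called on withdrawal were called in the opposite direction at some time of GDNF return, in comparisons that share the withdrawal arrays. Of 1533 probe sets that fell on withdrawal, 1077 (70.3%) rose over withdrawal at 2, 4 or 8 h, and 172 were lower still at some time. Among the 1077 were the probe sets that represent 676 genes. Of 1809 that rose, 1396 (77.2%) fell again. The largest reversals in the set that fell were those of Fblim1, Anxa3, Bcl6b, Ccsap, Arap3, Trib1, Gpx2, Selenom, Nos3 and Upk1b. Selenom fell 3.48-fold and rose at most 3.11-fold, and Upk1b, a uroplakin gene, fell 3.03-fold and rose at most 3.73-fold. Anxa3 fell 2.48-fold and rose 2.46-fold at 8 h with values under 16 set to 16, and Ccsap fell 2.37-fold and rose 2.61-fold, below Selenom, Nos3 and Upk1b, so their place in this order depends on the lowest intensities. Of these 10 genes Bcl6b, Trib1 and Gpx2 were already higher at 2 h (adjusted p = 1.37e-06, 9.47e-05 and 0.000431), and Bcl6b, Gpx2, Nos3 and Trib1 were still below the control at 8 h. For Trib1 this call was lost without control replicate 1 or 3 or 8 h replicate 2 (adjusted p = 0.0624, 0.0617 and 0.0856), without the low-value filter (0.0597) and with only the groups compared (0.0517). Of the 1533 probe sets that fell, 436 were still lower than in the control at 8 h, 70 were higher and 1027 were not called, and their median log2 change against the control went from -0.364 on withdrawal to -0.117 at 8 h. These probe sets were chosen as lower than the same control arrays, so part of these counts and medians may come from that choice.

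Both comparisons in this overlap use the withdrawal arrays, which pushes their log2 changes in opposite directions by chance. Independent lists would share 334 probe sets for the fall and rise and 481 for the rise and fall, while 100 simulations of unchanged groups gave 0 in each, because almost no probe set passes the threshold when nothing changes, which does not gauge the shared arrays. The covariance of the log2 changes on withdrawal with those at 2, 4 and 8 h was -0.0320, -0.0496 and -0.0513, against simulated medians of -0.00659, -0.00591 and -0.00548 and simulated lowest values of -0.0207, -0.0184 and -0.0209. The correlations across genes were -0.422, -0.575 and -0.650, against simulated medians of -0.538, -0.507 and -0.45, and all lay within the simulated ranges of -0.904 to 0.156, -0.96 to 0.284 and -0.914 to 0.466. Genes are not independent replicates, 3 withdrawal arrays cannot be split into groups of 2, and part of the excess may come from the shared arrays. The comparison of 8 h with 2 h does not use the withdrawal arrays. In it 497 of the 1533 probe sets that fell were higher and 230 lower. Of the 1809 that rose, 160 were higher and 423 lower, against 1874 higher and 2283 lower among all 15856. This covers movement between 2 h and 8 h alone.

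**Figure D4:**
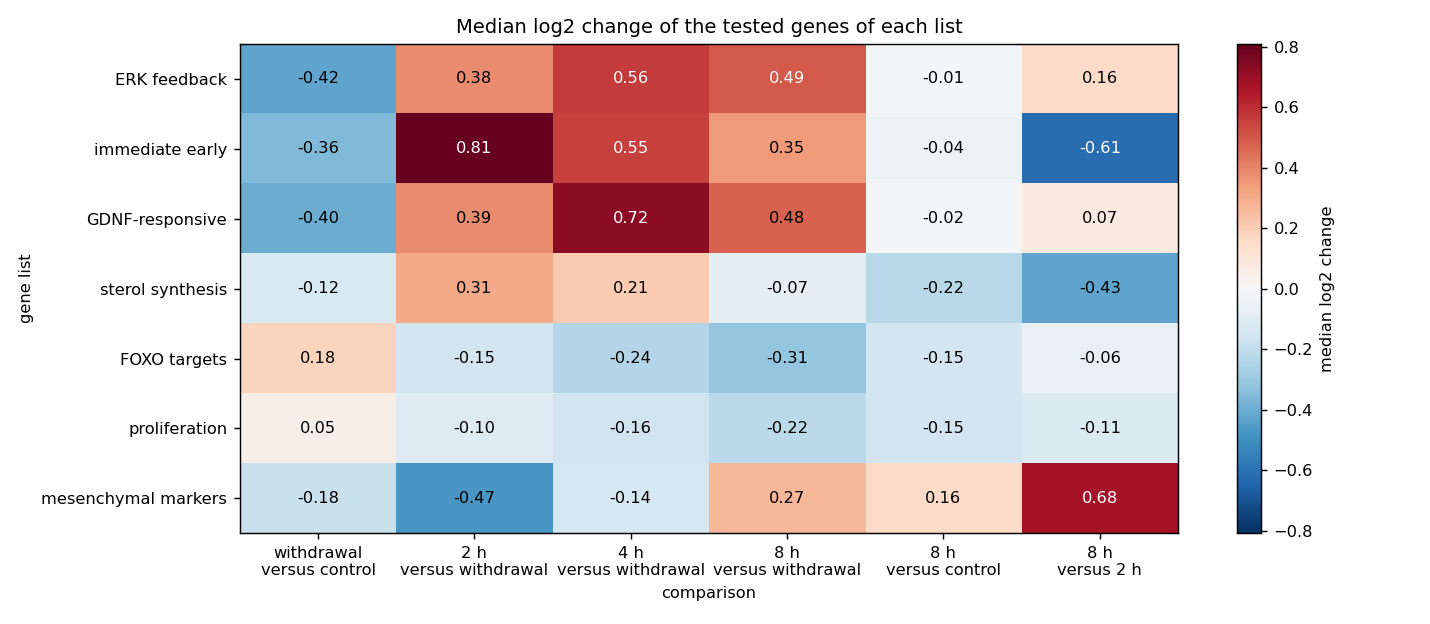
Median log2 change of the tested genes of 7 lists (rows) in the 6 comparisons (columns); colour and number give the median, red higher and blue lower in the first-named group. The immediate early list had a median of 0.81 at 2 h and 0.35 at 8 h over withdrawal, and the sterol synthesis list 0.31 and -0.07.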

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

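Of the tests in this part, those of a different share of mesenchymal cells in all 3 patterns, the covariate they use, the bound for a fall within mesenchymal cells and the condition of leaving out single arrays in the scaling test were chosen or reworded only after the result was seen.

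For 40 genes named at 2 h or 8 h after GDNF return, the log2 change over withdrawal differed between these times, by the limma comparison of 8 h with 2 h at an adjusted p under 0.05. The change at 8 h minus that at 2 h was 3.54 for S100a3, 3.21 for Myh2, 2.42 for Fblim1, 2.17 for Plcd4, 2.05 for Epas1, 2.03 for Meis1, 1.98 for Ccsap, 1.88 for Anxa3, 1.71 for Hoxa5, 1.6 for Zfhx4, 1.34 for Gfra3, 1.29 for Pdgfra, 1.25 for Cdkl4, 1.22 for RT1-T24-4 and 1.17 for Plaur. Smaller positive differences were 0.844 for Ccnd2, 0.687 for Bcl6b, 0.686 for Cxcr4, 0.624 for Chac1, 0.624 for Etv5, 0.335 for Atoh8 and 0.313 for Ret, whose other probe sets gave no such difference. Atoh8 lay under 16 on every array at both times, so its difference has no measured direction, and with values under 16 set to 16 those of S100a3, Ccsap and Plcd4 were 2.08, 1.38 and 1.07 (adjusted p = 0.066 for Plcd4). The difference was -4.13 for Egr2, -3.4 for Fosb, -1.7 for Epb41l5, -1.31 for Fos, -1.27 for Junb, -1.09 for Trib1, -1.07 for Crip2, -1.06 for Zcchc18, -1.02 for Bik and -1.02 for Krt12. It was -0.86 for Vat1, -0.829 for Foxo3, -0.779 for Sfn, -0.774 for Fhl2, -0.739 for Smad7, -0.656 for Slc24a4, -0.655 for Hspa1a and -0.527 for Rac2. With the mesenchymal marker mean as a covariate, Fos and Trib1, at -0.361 and -0.43, were no longer past the threshold (limma adjusted p = 0.488 and 0.323). Nor were Hoxa5 (0.604, adjusted p = 0.131), Pdgfra (0.361, 0.0565), Plaur (0.212, 0.477), Chac1 (0.758, 0.0532), Vat1 (-0.577, 0.127), Fhl2 (-0.912, 0.0501), Smad7 (-0.574, 0.096), Hspa1a (-0.299, 0.373) and Rac2 (-0.393, 0.224), while Fosb was at -2.01, Meis1 at 1.16 and Zfhx4 at 0.619. The mean did not overlap between 2 h and 8 h and contains Pdgfra, so these lost calls do not show a mesenchymal source. Leaving out 1 array also ended calls: that of Chac1 without 2 h replicate 1 or 3 or 8 h replicate 1 (adjusted p = 0.0578, 0.0782 and 0.0803), and that of Fhl2 without 2 h replicate 2 or 3 or 8 h replicate 2 (0.0543, 0.0695 and 0.0604) or with only the groups compared (0.0537). The same held for Rac2 without replicate 1 of 2 h or 8 h (0.0658 and 0.0595), Hspa1a without 8 h replicate 2 or 3 (0.06 and 0.054) and Atoh8 without 2 h replicate 3 (0.0521). Among all tested probe sets, 1718 were called at both times against withdrawal, and 124 of these in opposite directions, 46 up and then down and 78 down and then up.

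By the same comparison 5 lists differed between 2 h and 8 h, with a median log2 difference of 0.676 for mesenchymal markers, 0.195 for receptor and proximal signalling genes, -0.109 for proliferation genes, -0.426 for sterol synthesis genes and -0.614 for immediate early genes. With an estimated correlation 0 of the 5 were called (adjusted p = 0.356, 0.137, 0.356, 0.0754 and 0.175 in that order). With the marker mean as a covariate the proliferation list was not called (0.158). The mesenchymal median was then 0.013 (adjusted p = 0.971), which says nothing of its source, since the covariate is the mean of these same markers. Control probe sets outside the tests also stood above the control cultures on every array of a group. The 5S ribosomal RNA probe set was at 1.62 times the control mean after withdrawal and 1.33 times at 2 h (2044 ± 45.8 and 1682 ± 28.4 against 1263 ± 58.4, SD, n = 3). The ratb1 probe set was at 1.27 times the control mean at 4 h and 2.12 times at 8 h (174.3 ± 24.4 and 292.4 ± 17.1 against 137.7 ± 10.1). The ratb2 probe set was at 1.1 times at 8 h, with all group means under the low-value level. Single arrays were not tested within the groups of 3.

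Mesenchymal markers were lower at 2 h than after withdrawal in 5 of 16 members, and neither explanation weighed was excluded. No technical source was weighed. The first component within groups followed the poly-A spike mean as well as the marker mean (Pearson r = 0.809 and 0.933, exact permutation adjusted p = 0.041 and 0.0142). The poly-A spike mean was 9.28 ± 0.147 after withdrawal and 9.213 ± 0.017 at 2 h, and the hybridization spike mean 10.112 ± 0.153 and 9.89 ± 0.165 (log2, SD, n = 3). A different share of mesenchymal cells would make members that follow the marker mean more steeply fall further, and across the 16 members the Pearson r of that slope in the control, 4 h and 8 h arrays with the fall was 0.338 (permutation p = 0.204; Spearman's rho 0.321, permutation p = 0.227; 95% bootstrap interval -0.236 to 0.762), so it may or may not hold. The wording fixed before this value was seen used the log2 change in place of the fall, so that the same relation would have counted against the explanation, which was wrong because the explanation predicts falls. A fall of the transcripts within mesenchymal cells also stays open: the 248 other genes that followed the mean averaged -0.275 at 2 h (-0.581 to -0.138 without any 1 array) and 0.101 with the mean as a covariate (0.0777 to 0.268 without any 1 array), and the first wording counted a value over -0.1 there as excluding it, which was wrong because the covariate also removes a fall that all mesenchymal transcripts share. With the covariate, Meis1, Hoxa5 and Zfhx4 were still lower by limma, at -1.06, -0.814 and -0.858. Pdgfra was at -1.18 with the mean of the other markers, without Pdgfra, as the covariate. GDNF return itself is untested as a cause.

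Sterol synthesis genes were higher at 2 h and lower at 8 h, a median difference of -0.426. With the marker mean as a covariate the median was -0.339 (-0.393 to -0.326 without any 1 array) and 12 members were lower (10 to 13), against 13 without it. Most of the difference thus stayed in this fit. It does not decide on a different share of mesenchymal cells, because the mean may not measure that share and did not overlap between 2 h and 8 h. Under the covariate the list was called by camera with the preset correlation (adjusted p = 5.37e-10) but not with an estimated one (adjusted p = 0.0567, and 0.0754 without the covariate). Medium exchange or handling at replacement cannot be told apart from the return of GDNF, because the number of groups with a medium exchange and no GDNF at a replacement time was 0, which holds for every change at 2, 4 or 8 h over withdrawal, immediate early genes included. GDNF return and the time since it are the biological explanation that the design gives. This and handling may each account for the pattern. Handling at the start of withdrawal was not weighed, and may enter the comparisons of withdrawal and 8 h with the control.

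Proliferation genes were lower at 8 h than in the control in 15 of 33 members. With the marker mean as a covariate 14 members were lower (8 to 14 without any 1 array). That mean was 8.483 ± 0.234 in the control and 8.6 ± 0.1 at 8 h (log2, SD, n = 3), so the covariate could change this comparison little. It therefore does not decide on a different share of mesenchymal cells. Under the covariate the list was called by camera with the preset correlation (adjusted p = 3.39e-06) but not with an estimated one (adjusted p = 0.118, and 0.165 without the covariate). Scaling between arrays may account for part: with each array centred on its median 8 members were lower (7 to 10 without any 1 array), with a median log2 change of -0.128 against -0.155 as deposited. As deposited the number was 7 to 15 without any 1 array, so the count alone does not decide, and the history of withdrawal and return is untested as a cause.

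The 6 arrays of each comparison can be split in 10 ways, the real one included, which is too few for a share under 0.05, and only the real split (1 of 10) gave as many calls in each. For withdrawal against control the real number was 3342 and the highest other 6; for 2, 4 and 8 h against withdrawal 4137, 4848 and 3963 against 1, 0 and 0; for 8 h against control 1953 against 1, and for 8 h against 2 h 4157 against 0. Over 100 groupings of the 15 arrays, 1, the real one, gave as many differences among the 5 groups (7864, the highest other 1642) and as many probe sets that fell and then rose (1077, the highest other 41). This argues against an absence of any difference among the groups. Other splits and groupings mix arrays of groups that differ, which widens their spread, so they do not gauge the reversal or the shared withdrawal arrays.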

How the results depend on the processing

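The mesenchymal marker covariate, 3 arrays left out together and the overlap without the 2 h arrays are the tests of this part chosen after the result was seen. Counts of called probe sets stayed within 1.5 times the reported values under all other filters, scalings, weights and trends tried, with these exceptions. With only the groups compared in the fit, 2166 were called on withdrawal and 1241 between 8 h and control, where fewer arrays estimate the spread. With the mesenchymal covariate 2329 were called between 8 h and 2 h. There the marker mean did not overlap between the groups, so the covariate takes up part of the contrast, and a mesenchymal source was not tested. Of the calls as reported, 95.4%, 75.8%, 95.6%, 83.8%, 97.8% and 45.3% were kept under this covariate in the 6 comparisons in the order of the report, and none was called in the opposite direction. Without any 1 array the counts ranged from 2476 to 2986 on withdrawal, 2832 to 3764 at 2 h, 3837 to 4485 at 4 h, 3022 to 3591 at 8 h, 1312 to 1694 for 8 h against control, 3015 to 3355 for 8 h against 2 h, 6878 to 7833 for any difference and 785 to 1110 for fall and rise. With 3 arrays left out they were 2416, 3995, 4030, 3311, 1620, 4428, 6954 and 893, and without the 2 h arrays 909 probe sets fell and then rose.

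The replicate number as a block gave 3520, 4291, 5047, 4129, 2047, 4315, 8125 and 1117 in the same order. Whether the numbers pair the arrays was not settled. Of 30 same-numbered pairs 8 had correlated deviations over 0.1 (-0.138 to 0.381, median 0.04). Of 15 arrays 7 were most like an array of another group with their own number. Among replicates 1 the correlation was 0.381 for withdrawal with 4 h, and 0.234 and 0.236 for control with withdrawal and with 4 h. The block added 1 gene call, that of Egr2 at 8 h (adjusted p = 0.0493), and 1 list call.

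Of 114 list tests 33 were called with the preset correlation, 10 with an estimated one and 65 with fry, which does not compare a list with other genes. The number was 30 with the mean over probe sets, 38 with no filter, 34 with the block, 34 with the covariate and 33 with 3 arrays left out. The heat shock list at 4 h turned from down to up with fry (adjusted p = 0.0321), and the cause was not tested. Mesenchymal markers turned direction under the covariate, which is made from them, at 2 h (adjusted p = 0.812) and between 8 h and 2 h (0.971). Of 180 changes of the genes with the largest changes, the GDNF-tied genes and Ret, none that was called turned direction under a setting that kept its probe set, and quantile normalization and median centring ended or added no call. For these genes in the other comparisons, the other list members and the genes of the fall and rise set, 284 of 828 calls were lost under at least 1 setting. Of these genes 3 mesenchymal markers (Bgn, Dcn and S100a4) turned direction without a call, between 8 h and 2 h under the covariate. With values under 16 set to 16, 31 of the 180 fold changes moved by over 1.5 times, so folds of genes near that intensity are limited by signal over background.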

Other observations

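The gene lists of this part and the mesenchymal marker mean as a quality measure were fixed before the data were examined. The poly-A spike mean was not in that plan. The test of the within-group component and the slopes on the mesenchymal marker mean were chosen after the result was seen.

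Markers of undifferentiated spermatogonia moved both ways on withdrawal, 8 of 15 lower and 4 higher (8 and 5 adjusted over the list alone, and camera adjusted p = 0.0682, or 0.0444 with 3 arrays left out). Of the 28 listed genes 7 stand in another list as well. Besides Bcl6b, the adhesion molecule gene Epcam fell 1.45-fold and the tetraspanin gene Cd9 1.29-fold, while the E-cadherin gene Cdh1 rose 1.38-fold. On return 3, 6 and 5 members were higher and 3, 5 and 4 lower at 2, 4 and 8 h (adjusted p = 0.979, 0.58 and 0.444), and the medians of -0.06, -0.07 and -0.01 had the opposite sign to the means of 0.05, 0.17 and 0.16. The integrin gene Itgb1 rose 1.67-fold at 4 h and 1.65-fold at 8 h (its other probe set by 0.44 on the log2 scale at 4 h), and Sox3 fell 1.68-fold at 8 h. Among genes of differentiating spermatogonia and early meiosis, 6 of 10 rose on withdrawal and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 0.152), the receptor gene Kit by 1.71-fold, and Kit fell 1.55-fold at 4 h and 1.53-fold at 8 h. Of 3 later germ cell markers Crem rose 1.32-fold on withdrawal (adjusted p of the list = 0.271), though its 3 other probe sets were not past the threshold (limma adjusted p = 0.978, 0.826 and 0.305). Of 16 arrest and apoptosis genes 7 rose and 3 fell on withdrawal (8 and 3 adjusted over the list alone, and camera adjusted p = 0.0682, fry 1.72e-09), the cell cycle inhibitor gene Cdkn1c by 1.96-fold and the p53 target Ccng1 by 1.83-fold, while Perp fell 2.58-fold. Camera called this list upward without the low-value filter (adjusted p = 0.0204) and with 3 arrays left out (0.0497). At 8 h 2 rose and 7 fell (2 and 8 adjusted over the list alone, and camera adjusted p = 0.101, fry 9.34e-10), Ccng1 2-fold and Cdkn1c 1.94-fold. Without the low-value filter camera called the list downward at 8 h (adjusted p = 0.0283).

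Other lists were not called in any comparison by camera, though single members moved. The interferon list (11 tested; adjusted p = 0.305 on withdrawal) held Gbp2, which fell 2.29-fold on withdrawal and rose 2.37-, 4.31- and 3.29-fold at 2, 4 and 8 h. The glycolysis and hypoxia list had 4 of 18 members higher and 7 lower on withdrawal (5 and 7 adjusted over the list alone; adjusted p = 0.217), with Adm 2.05-fold lower, and the angiogenic factor gene Vegfa rose 2.58-fold at 2 h and the glucose transporter gene Slc2a3 2.92-fold at 4 h. In the heat shock list (15 tested; adjusted p = 0.321) the heme oxygenase gene Hmox1 fell 1.46-fold and rose 1.47-, 2.58- and 1.69-fold, opposite to Hspa1a at each step. In the amino acid response list (18 tested; adjusted p = 0.505) Sesn2 rose 1.53-fold on withdrawal and fell 1.33-, 1.73- and 1.66-fold. Of 26 ribosome biogenesis genes 4 rose and 1 fell on withdrawal, also adjusted over the list alone (adjusted p = 0.321), with Cad 1.28-fold higher, whose other probe set was not past the threshold (adjusted p = 0.0504). Among Sertoli cell markers Wt1 rose 2.14-fold at 4 h and 1.42-fold at 8 h, the latter call lost without withdrawal replicate 1 or 2, 8 h replicate 1 or 3, the low-value filter or 3 arrays (limma adjusted p = 0.056, 0.0842, 0.0976, 0.0596, 0.0541 and 0.0687). The only Leydig and peritubular marker tested, Acta2, was not called in any of the 6 comparisons, and no immune or blood marker passed the low-value filter.

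The median and mean of a list also differed in sign for the glycolysis, interferon, Sertoli and ribosome lists at 2 h and 4 h, the heat shock list at 2 h and against control, the differentiating list at 4 h and 8 h, the receptor list against control, and the amino acid and ribosome lists between 8 h and 2 h. The direction of camera or fry differed from both for the late germ cell list at 2 h, the ribosome list at 8 h, the heat shock list at 4 h and the immediate early list against control, and fry was opposite to the rest for the receptor list at 2 h and the late germ cell list at 4 h. None of these was called by camera.

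Within groups, the first component of the arrays held 25.0% of the variance and followed the mesenchymal marker mean (Pearson r = 0.933, exact permutation p = 0.00129, adjusted 0.0142 over 11 relations; Spearman's rho 0.946, exact p = 0.0009), with r = 0.887 without the 2 arrays farthest from the median. It also followed the poly-A spike mean (r = 0.809, exact permutation p = 0.00746, adjusted 0.041; rho 0.746, exact p = 0.0213; r = 0.805 without the 2 farthest). Of the 16 list members 12 followed the marker mean upward by limma, but each is part of that mean, so a positive slope is partly built in. Of 8986 genes outside the list 248 followed the marker mean upward and 54 downward. The steepest, chosen after their values were seen, were Tbc1d19, Pmp22, Ass1 and Rnd3, with log2 slopes of 1.98, 1.97, 1.93 and 1.92, beside the chemokine gene Cxcl12 at 1.86 and the cytokine gene Csf1 at 1.91.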
